A study of Homo sapiens with 6 samples.

How the data were processed

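The 3' ends of polyadenylated RNA were counted in 6 A-seq libraries of HEK293 cells, a human embryonic kidney cell line. A-seq selects poly(A) RNA, breaks it into fragments and primes reverse transcription at the junction of the transcript body and its poly(A) tail, so that each read ends at a cleavage site. Fragments were made by alkaline hydrolysis in 4 libraries (no siRNA, scrambled siRNA, CF Im25 siRNA, CF Im59 siRNA) and by RNase I in 2 libraries (scrambled siRNA, CF Im68 siRNA). Cells that received siRNA were harvested after 3 days. Each group held 1 library.

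The deposited files give counts: for each nucleotide and strand, the number of reads whose 3' end lies there. The authors left these counts unscaled, as whole numbers, and each file holds 1 library. The submitters' processing notes name the builds hg19 and GRCh37, and positions on chromosome 1 reached 249229753. The aligner, the read filters, and any removal of duplicate reads or of internally primed reads are not given in the sources used here. Library totals were 18183644 reads (no siRNA), 9690883 (scrambled siRNA, alkaline), 10659900 (CF Im25 siRNA), 12642699 (CF Im59 siRNA), 5351980 (scrambled siRNA, RNase I) and 12997383 (CF Im68 siRNA).

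Poly(A) sites were called once for all libraries. The 6 libraries were pooled at equal weight, the highest remaining position was taken as a site together with all ends within 25 nt on either side, and this was repeated until no position was left. Sites with a mean CPM (reads scaled to the library total) of at least 1 over the 6 libraries were kept. Of 2438055 positions, this left 49965 sites, of which 49695 were nuclear, and these sites held between 91.5% and 92.7% of the reads of each library. Annotation and genome sequence of the files' build were not used here, and coordinates were not converted between builds. Sites on the same strand with gaps of at most 5 kb were therefore joined into a unit, and loci are named by hg19 coordinates. In each unit the 2 most used sites were compared where each held at least 5% of the reads of the unit in the mean over libraries. Of 28114 units, 8999 (32.0%) gave such a pair, with a median distance of 1141 nt (interquartile range 296 to 2598 nt). A unit can join the ends of neighbouring transcripts, and it is not a gene.

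The proximal share is the percentage of the reads at the 2 sites that lie at the upstream one. A locus was called shifted when its share changed by at least 20 percentage points, both libraries held at least 50 reads over the 2 sites, and the 95% Newcombe interval of the difference excluded 0. Total reads of a unit were scaled to the library's reads in all nuclear units, and a unit was called higher or lower at a 2-fold difference with at least 50 reads in 1 of the libraries and an exact 95% interval of the ratio that excluded 1. With 1 library per group there is no replicate error and no p-value across loci, so both rules are rules of size. Intervals for shares of loci are exact binomial (Clopper-Pearson). Intervals for a single locus or unit cover the counting error of reads only, since each group held 1 library. Intervals for shares of loci, for numbers of calls by chromosome and for calls between neighbouring units treat loci or calls as independent trials. Loci are not independent replicates, and no interval covers the spread between libraries. Copies of a molecule made by PCR are not independent, and removal of duplicates is not given, so the intervals can be too narrow. Where a library had no reads in a unit the ratio is not finite, and the limit of the exact 95% interval nearer to 1 is given as a bound.

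Each knockdown was compared with the scrambled siRNA library of its own fragmentation method, and the comparison of no siRNA with scrambled siRNA gave the differences seen without a targeting siRNA. Where a pair of comparisons used the same control library, the changes were also simulated 100 times from the pooled share of each locus with an overdispersion of 0.0182, estimated from the no siRNA and scrambled siRNA libraries, to give the covariance that the shared control produces alone. Total reads were simulated likewise, and their correlations used log2 ratios with 0.5 reads added to each count. The totals of shifted loci were compared with 10000 random lists of tested pairs of similar level. The rules of size, the minimum reads, the comparisons and the conditions for named loci were fixed before the data were examined. The plan had set longer lists of annotated genes, and shorter lists of units are given in their place. For each knockdown, the 3 loci with the largest rise and the 3 with the largest fall in proximal share are named. These were called loci with at least 100 reads in each library. For CF Im25 and CF Im59 they had also to change in the same direction against no siRNA. For total reads the 3 largest rises and the 3 largest falls with at least 100 reads in one library are named, without a condition on no siRNA. Units with 0 reads in either library of a comparison ranked first, in order of their reads, an order set after the data were seen. Total reads of units took the place of gene-level expression after the data were examined. Other loci that are named were chosen after their values were seen.

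The steps were tested on simulated data with counting error only. The planted sites were wholly simulated, and the planted shifts and changes in total reads used the levels of the real loci and units. All 2000 planted sites were found. These were planted so far apart that their windows did not overlap, with no background reads, so close sites and background were not tested. Of 100 planted shifts of 30 points per comparison, 98 were recovered for CF Im25, 98 for CF Im59, 97 for CF Im68 and 96 for no siRNA against scrambled siRNA, with 10, 11, 1 and 8 false calls among the unchanged loci. Since no overdispersion was simulated, these false calls do not give the rate between real libraries. The real no siRNA and scrambled siRNA libraries gave 87 proximal and 181 distal calls at 7177 loci. All planted changes of 40 points, and all 3-fold changes in total reads, were recovered.

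Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. R 4.3.3 with edgeR 4.0.16 was used for TMM scaling factors alone. The alternatives tried were narrower and wider sites, a lower minimum of reads, a higher minimum for the minor site, no minimum level of a site, all sites of a unit in place of a pair, thinning of all libraries to the smallest total (counts are the mean of 10 random draws), the no siRNA library as control, TMM and median of ratios scaling, and no minimum for total reads. The scalings, the alternative without a minimum and the no siRNA control for total reads had been set for annotated genes and were applied to units after seeing the data. Other alternatives added after seeing the data were other gaps between units, sites called from libraries of the same fragmentation method, the rule passed against both controls, and removal of sites with nearly all reads at 1 nucleotide. Thinning for total reads was also added then. The removal of sites next to A-rich genomic sequence, counts of the UGUA motif, gene-level expression, the levels of the siRNA targets, gene lists and cell type markers all need annotation or sequence of the files' build, and were not analysed here. Counting distinct alignments in place of reads was left out because the counts hold no copy numbers, and a longer reach beyond annotated ends was left out with the annotation.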

Results

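Cleavage sites of polyadenylated RNA were counted in HEK293 cells after siRNA against 1 of 3 subunits of cleavage factor Im, the complex that binds nascent RNA upstream of poly(A) sites. CF Im25 is its smaller subunit, and CF Im59 and CF Im68 are its larger ones. The series was titled as a study of how this factor relates to the length of 3' UTRs, and the comparisons ask in which direction poly(A) site use moved after each siRNA. There was 1 library per group, with 5351980 to 18183644 reads, so no difference could be checked against a spread between replicates. Whether each target protein was lost was not analysed here. Over the 4779 loci with at least 50 reads at both sites in every library, the median proximal share was 33.9% without siRNA, 36.8% with scrambled siRNA, 49.3% with CF Im25 siRNA and 33.6% with CF Im59 siRNA in the alkaline libraries. In the RNase I libraries it was 38.2% with scrambled siRNA and 58.7% with CF Im68 siRNA.

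Without a targeting siRNA, poly(A) site use differed little between the alkaline control libraries. Of 7177 loci tested for no siRNA against scrambled siRNA, 87 (1.21%, interval 0.972 to 1.49) had a higher proximal share and 181 (2.52%, interval 2.17 to 2.91) a lower one. The median change was -1.15 points. Changes of at least 40 points were seen at 1 locus towards the proximal site and at 3 loci towards the distal site. These counts are the background for the alkaline knockdowns, and no such pair of controls was sequenced with RNase I.

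After CF Im25 siRNA, poly(A) site use moved towards the proximal site. Of 6702 loci, 1227 (18.3%, interval 17.4 to 19.3) shifted to the proximal site and 188 (2.81%, interval 2.42 to 3.23) to the distal site. The proximal share was higher than in the control at 65.8% of the loci, with a median change of 4.19 points, and the median change of the loci called proximal was 30.9 points. Changes of at least 40 points were 309 towards the proximal and 21 towards the distal site. Against the no siRNA library, which has the larger depth, 1472 of 7209 loci shifted proximally and 141 distally, and 1022 of the 1224 proximal loci that could be tested against both controls passed against both (83.5%). Of the distal loci, 79 of 188 passed against both (42.0%).

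The 3 largest rises after CF Im25 siRNA lay on chromosomes 9, 2 and 17. On the minus strand of chromosome 9, the site at 104152248 rose from 16.1% of 161 reads to 89.4% of 199 reads against the site at 104149916, a change of 73.3 points (interval 65.1 to 79.3), with 17.0% in the no siRNA library. The same proximal site already held 95.6% in the RNase I library with scrambled siRNA, so its baseline differed between the fragmentation methods. On the minus strand of chromosome 2, the site at 38523045 rose from 23.1% to 94.7% against 38521105 (71.6 points, interval 62.2 to 78.8), and its share was 42.1% and 97.8% in the RNase I libraries with scrambled and CF Im68 siRNA. The chromosome 17 minus strand site at 62541465 rose from 18.1% to 87.1% against 62538423 (69.0 points, interval 60.3 to 75.4). The largest falls were on chromosome 6 plus strand (46645926 against 46648068, from 94.3% to 43.5%), chromosome 14 plus strand (24907610 against 24910546, from 78.8% to 33.8%) and chromosome 1 minus strand (78414090 against 78409741, from 94.3% to 49.8%). With CF Im59 siRNA the share at the chromosome 14 locus was 35.6%.

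After CF Im68 siRNA, site use also moved towards the proximal site. Of 5291 loci, 1291 (24.4%, interval 23.2 to 25.6) shifted to the proximal site and 94 (1.78%, interval 1.44 to 2.17) to the distal site. The proximal share was higher at 72.0% of the loci, the median change was 5.51 points, and the loci called proximal had a median change of 35.3 points. Changes of at least 40 points were 521 towards the proximal and 8 towards the distal site. The control library had 5351980 reads, the fewest of the 6.

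At the loci with the largest rises after CF Im68 siRNA the main site was replaced. On the plus strand of chromosome 2, the site at 178403013 rose from 8.22% of 292 reads to 97.6% of 629 reads against 178406782 (89.4 points, interval 85.4 to 92.2). Its share was 5.35% with scrambled siRNA, 52.0% with CF Im25 siRNA and 2.84% with CF Im59 siRNA in the alkaline libraries. On the plus strand of chromosome 8, the site at 95802348 rose from 2.78% to 90.5% against 95806062 (87.7 points, interval 81.6 to 90.8), and stood at 2.75%, 39.7% and 2.92% in the same alkaline libraries. The chromosome 1 minus strand site at 54233394 rose from 3.86% to 89.7% against 54231158 (85.9 points, interval 83.2 to 88.1). Its alkaline values were 24.2%, 90.3% and 36.2%. The largest falls were on chromosome 6 minus strand (170107140 against 170104004, from 69.3% to 17.4%), chromosome 2 plus strand (178086110 against 178086899, from 53.2% to 1.71%) and chromosome 12 plus strand (72096968 against 72097836, from 55.4% to 8.44%). The same 3 loci fell after CF Im25 siRNA, with changes of -30.3, -41.8 and -29.4 points, while their shares with CF Im59 siRNA were 66.3%, 57.8% and 81.3% against 61.9%, 45.5% and 84.0% with scrambled siRNA.

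**Figure D1:**
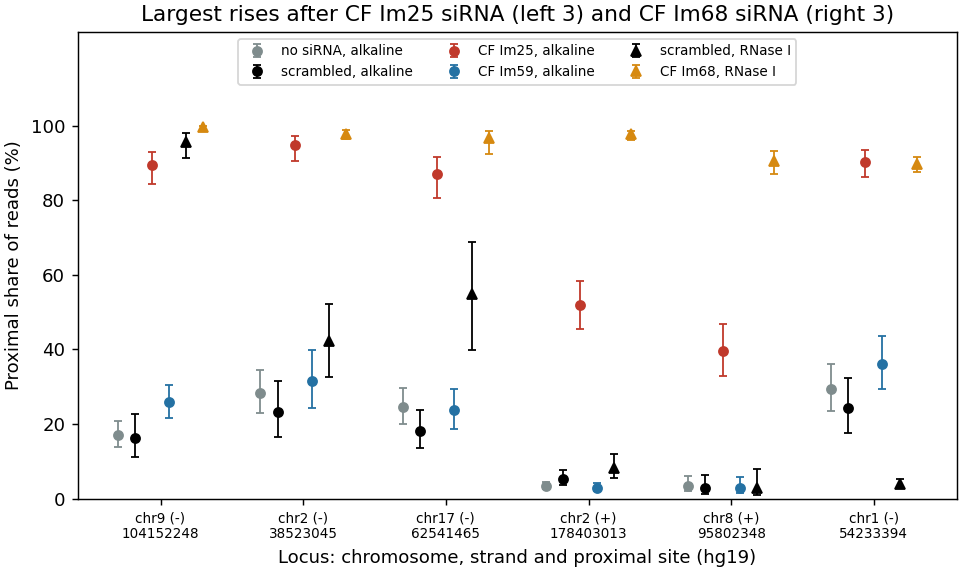
Proximal share of reads (vertical axis, percent) in the 6 libraries at the 3 loci with the largest rise after CF Im25 siRNA and the 3 after CF Im68 siRNA, named by chromosome, strand and hg19 position of the proximal site; circles are alkaline and triangles RNase I libraries, and bars are 95% Wilson intervals of counting error. CF Im68 siRNA brought the chromosome 2 plus strand locus to 97.6%, and CF Im25 siRNA brought it to 52.0%.

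The calls after CF Im25 and CF Im68 siRNA overlapped in part, in comparisons that share no library. Over 4815 loci tested in both, Pearson's r of the changes was 0.536 and Spearman's rho 0.499, across loci, which are not independent replicates. Of these loci 858 were called proximal after CF Im25 siRNA and 1186 after CF Im68 siRNA. Both siRNAs shifted 506 loci proximally, where independent calls would share 211, and 19 loci distally, where independent calls would share 1.72. Of the loci called proximal after CF Im25 siRNA, 95.9% had a higher share after CF Im68 siRNA, against 72.9% of all loci, and their median change there was 26.4 points. Called in opposite directions were 3 loci.

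**Figure D2:**
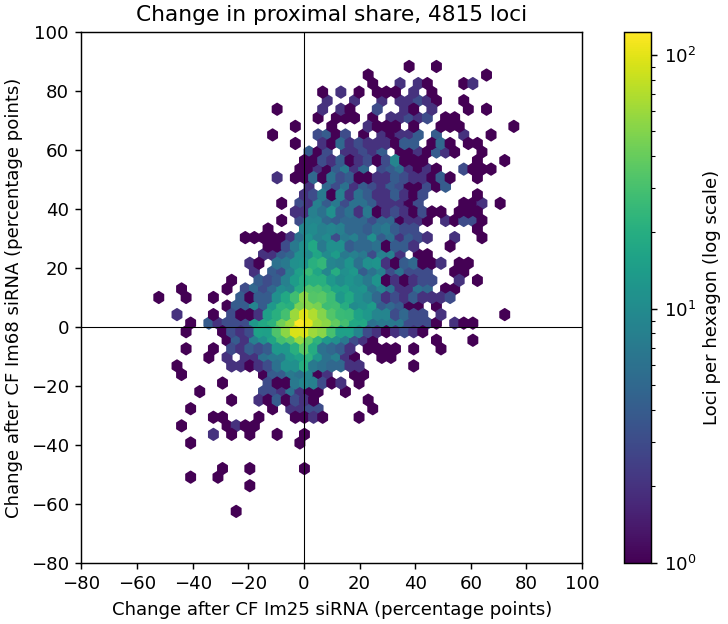
Change in proximal share (percentage points) after CF Im25 siRNA (horizontal axis) and after CF Im68 siRNA (vertical axis) at 4815 loci; colour gives the number of loci per hexagon on a log scale. Most changes lie at or above 0 on both axes, with r = 0.536 across loci.

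After CF Im59 siRNA no shift towards the proximal site was seen. Of 6889 loci, 174 (2.53%, interval 2.17 to 2.92) shifted proximally and 328 (4.76%, interval 4.27 to 5.29) distally, with a median change of -1.19 points, close to the -1.15 points of no siRNA against the same control. Against no siRNA, 121 of 7489 loci shifted proximally and 156 distally, with a median change of -0.0619 points. Of the distal loci, 57 of the 327 tested against both controls passed against both (17.4%), and of the proximal loci, 46 of 173 (26.6%). The 3 largest rises lay on the minus strand of chromosome 17 at 8043790 against 8040093 (from 19.2% to 70.5%, and 56.6% without siRNA) and at 8131140 against 8123255 (from 33.7% to 79.4%, and 58.4% without siRNA), and on the minus strand of chromosome 8 at 24809889 against 24808480 (from 32.4% to 72.1%, and 25.9% without siRNA). The largest falls lay on chromosome 18 plus strand at 32824063 against 32829770 (from 72.9% to 22.9%, and 42.3% without siRNA), chromosome 12 minus strand at 49332494 against 49315752 (from 91.7% to 43.3%, and 83.2%) and chromosome 10 minus strand at 98985140 against 98981939 (from 49.5% to 4.62%, and 18.0%).

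**Figure D3:**
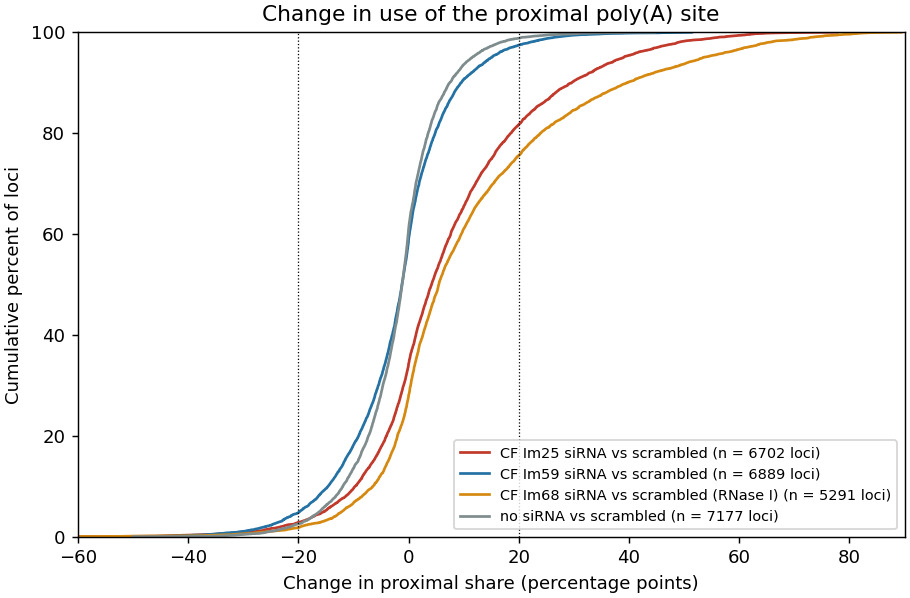
Cumulative percent of loci (vertical axis) by change in proximal share in percentage points (horizontal axis) for each knockdown and for no siRNA against scrambled siRNA; dotted lines mark changes of 20 points in either direction. The curves of CF Im25 and CF Im68 siRNA lie to the right of those of CF Im59 siRNA and no siRNA, with medians of 4.19, 5.51, -1.19 and -1.15 points.

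The changes after CF Im59 siRNA showed little relation to those after CF Im68 siRNA (r = -0.06 over 4859 loci). CF Im25 and CF Im59 siRNA were compared with the same control library, so their changes share its error. Over 6612 loci r was 0.461, where the shared control alone gave 0.509 in simulation, and the covariance was 77.3 against a simulated 37.3. Both shifted 115 loci proximally, where independent calls would share 28.2 and the simulation 20.1, and 76 loci distally, where independent calls would share 8.32 and the simulation 21.7. Part of this excess may come from the shared control. With CF Im25 siRNA against no siRNA and CF Im59 siRNA against scrambled siRNA, r was 0.145, and with the controls exchanged it was 0.283. Then 68 or 42 loci were proximal in both, against 30.5 or 14.9 from independent calls. Distal in both were 23 or 17, against 5.14 or 2.81. Proximal after CF Im25 siRNA but distal after CF Im59 siRNA were 73 or 14 loci, and 2 or 0 were the reverse. CF Im59 siRNA and no siRNA, each against scrambled siRNA, had r = 0.654, with 0.521 in simulation, and a covariance of 56.2 against a simulated 38.0.

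The proximal shift depended on how far apart the sites lay. After CF Im25 siRNA, 3.36% of pairs under 100 nt apart shifted proximally, and this rose to 11.7% from 100 nt, 15.9% from 200 nt, 20.4% from 500 nt and 25.4% from 1000 to under 2000 nt, with 22.1% from 2000 nt and 20.9% from 5000 nt. For CF Im68 siRNA the same distances gave 3.67%, 9.95%, 20.9%, 29.5%, 38.4%, 29.9% and 21.2%. For no siRNA against scrambled siRNA the share was between 0.214% and 2.00% at all distances. In units with exactly 3 sites, use moved from the last site to the first after CF Im25 siRNA, with mean changes of 7.57 points at the first, -0.264 at the middle and -7.31 at the last site of 1427 units. After CF Im68 siRNA they were 11.7, -0.322 and -11.4 points in 1086 units, and after CF Im59 siRNA -1.14, -1.50 and 2.64 points in 1467 units, with -0.967, -1.14 and 2.11 points for no siRNA against scrambled siRNA.

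**Figure D4:**
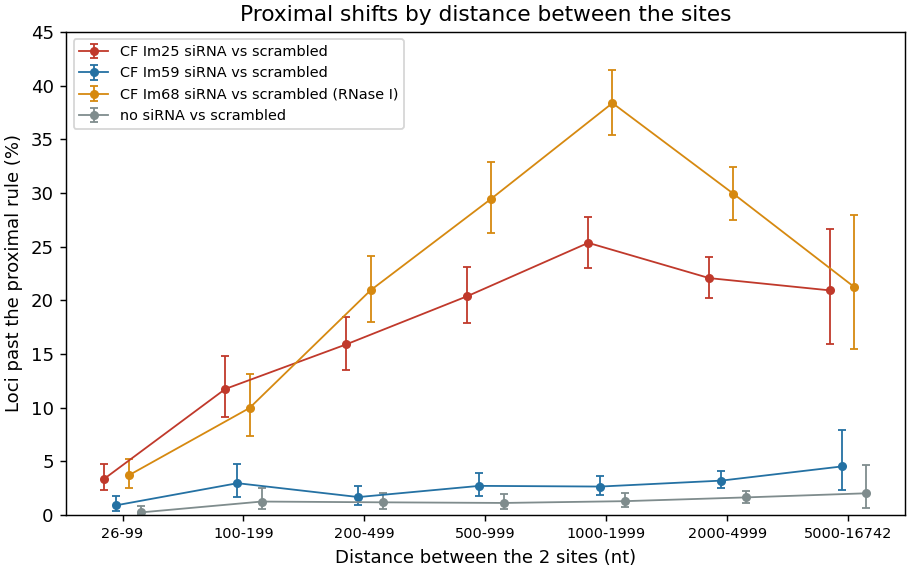
Percent of loci shifted to the proximal site (vertical axis) by distance between the 2 sites in nt (horizontal axis) for each knockdown and for no siRNA against scrambled siRNA; bars are exact 95% binomial intervals. The share was highest from 1000 to under 2000 nt, at 25.4% after CF Im25 siRNA and 38.4% after CF Im68 siRNA.

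Loci that already used mostly the proximal site shifted least often. Grouped by their share in the no siRNA library, which is not part of the comparison, 18.0% of loci with a share under 20% shifted proximally after CF Im25 siRNA, 28.3% of those from 20 to 50%, 18.3% of those from 50 to 80% and 2.16% of those above 80%. A share above 80% leaves no room for a rise of 20 points unless the control library lay lower. For CF Im68 siRNA, grouped by the alkaline scrambled siRNA library, the values were 29.3%, 27.6%, 21.5% and 14.6%.

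Proximal shifts were unevenly spread over chromosomes, a comparison chosen after the counts by chromosome were seen. After CF Im25 siRNA, chromosomes 16 and 19 had the lowest percentages of loci shifted proximally (9.03% and 10.1%), and chromosomes 13 and 18 the highest (28.1% and 26.6%). After CF Im68 siRNA, chromosomes 19, 16 and 22 had the lowest (9.12%, 11.3% and 11.5%), and chromosomes 4 and 8 the highest (37.5% and 36.0%). Across 23 chromosomes the percentages after CF Im25 and CF Im68 siRNA were correlated, with r = 0.801 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give) and rho = 0.749 (permutation p = 6e-05). This was the only relation computed across chromosomes, so Benjamini-Hochberg adjustment has nothing to change, but it was prompted by the counts and its p-values are not those of a planned test. Without chromosomes 16 and 13, the farthest from the median after CF Im25 siRNA, r was 0.825. Without the 3 lowest (16, 19 and 22) it was 0.599. The percentages also rest largely on the same loci, since 4815 were tested in both comparisons, with r = 0.536 across loci. Such agreement at single loci can make the percentages correlate, and permuting chromosomes removes it too. The permutation test therefore cannot separate a pattern of chromosomes from agreement at single loci.

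**Figure D5:**
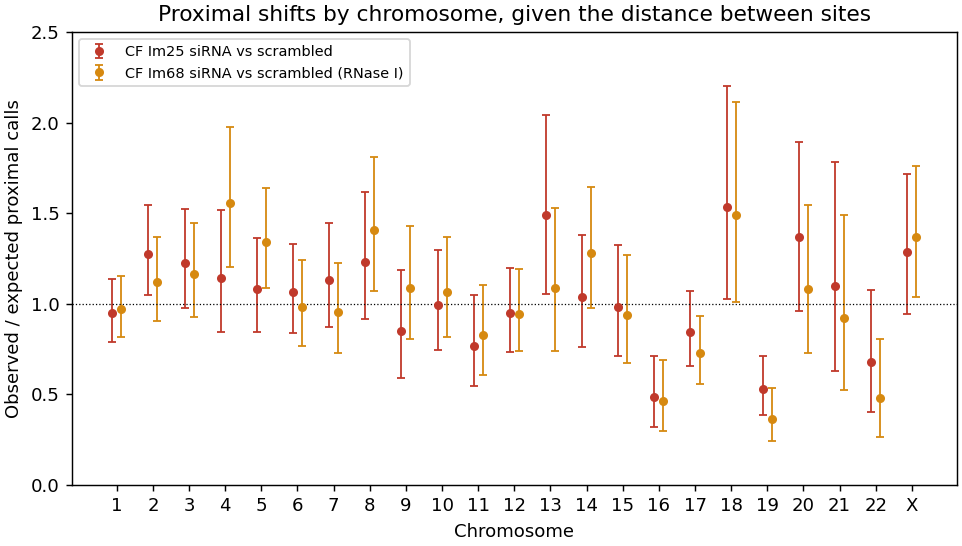
Observed over expected number of proximal shifts (vertical axis, ratio) per chromosome (horizontal axis) after CF Im25 and CF Im68 siRNA, with the expected number taken from the rate of all loci at the same distance between sites; bars are exact 95% Poisson intervals. Chromosomes 16 and 19 had ratios of 0.487 and 0.530 after CF Im25 siRNA, and 0.462 and 0.365 after CF Im68 siRNA.

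Total reads per unit, a measure of transcript level, changed in both directions after each siRNA. After CF Im25 siRNA, 1968 of 14983 units were higher and 1810 lower by at least 2-fold, and after CF Im59 siRNA 1314 of 15257 were higher and 1695 lower. After CF Im68 siRNA 1511 of 13531 were higher and 942 lower, and for no siRNA against scrambled siRNA 721 of 16791 were higher and 722 lower. Loci that shifted proximally after CF Im25 siRNA had slightly higher ratios of total reads than all pairs. Their median log2 ratio was 0.04 against -0.03, a small difference but above all of 10000 random lists. Loci that shifted distally after CF Im25 siRNA had a median of 0.03, at percentile 90.2. Against no siRNA the medians were 0.17 for proximal and 0.31 for distal loci, with 0.09 for all pairs. Higher totals were therefore not particular to the proximal shifts after CF Im25 siRNA. After CF Im68 siRNA the medians of proximal loci and all pairs were -0.04 and -0.07, at percentile 92.7 of the random lists. Its distal loci had a median of -0.23, at percentile 3.29. The balance of higher and lower units was not settled after CF Im59 or CF Im68 siRNA. Of the changed units 43.7% were higher after CF Im59 siRNA, but 53.1% with TMM and 52.7% with median of ratios scaling, and 39.8% with thinning. For CF Im68 siRNA 61.6% were higher, but 76.0% with TMM and 75.2% with median of ratios scaling, and 48.3% with all libraries thinned to the smallest total. With no minimum reads, 2037 units were higher and 3285 lower after CF Im68 siRNA. For no siRNA against scrambled siRNA, where the counts were 721 and 722, 63.4% were higher with TMM and 63.9% with median of ratios scaling, but 40.3% with thinning. TMM scaling moved all units by 0.18 on the log2 scale after CF Im68 siRNA and by 0.11 for no siRNA against scrambled siRNA.

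The largest rises in total reads after CF Im68 siRNA were on chromosomes 22, 12 and 3. On the minus strand of chromosome 22, the site at 22123332 rose from 0.427 to 22.0 CPM (reads scaled to the library's reads in nuclear units) after CF Im68 siRNA (2 and 241 reads, 51.6-fold, interval 14.1 to 428) and stood at 0.346 with scrambled and 11.99 with CF Im25 siRNA in the alkaline libraries. On the plus strand of chromosome 12, the unit from 19706154 to 19707336 rose 27.0-fold (4 and 252 reads, interval 10.4 to 99.7), with 1.27 and 12.6 CPM in those alkaline libraries. The chromosome 3 minus strand site at 120048827 was at 9.22 CPM after CF Im68 siRNA with 0 reads in its control, at least 11.5-fold higher, and had 2 reads with scrambled and 14 with CF Im25 siRNA in the alkaline libraries. The largest falls were on chromosome 5 minus strand at 43526372 (from 22.4 to 1.10 CPM), chromosome 20 plus strand at 57026155 (from 21.3 to 1.28) and chromosome 15 minus strand from 83508279 to 83511077 (from 43.3 to 2.65). With scrambled and CF Im25 siRNA in the alkaline libraries these stood at 13.1 and 1.24 CPM, 9.10 and 2.38 CPM, and 16.5 and 9.93 CPM.

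After CF Im25 siRNA the largest rises in total reads, with units of 0 control reads ranked first, were on chromosome 12 minus strand at 5863900 (441 reads against 0, at least 107-fold), chromosome X minus strand at 137751500 (192 against 0, at least 46.3-fold) and chromosome 6 plus strand at 12212985 (174 against 0, at least 41.9-fold). Of the reads at these sites, 95.9%, 100% and 100% lay at 1 nucleotide. The CF Im59 siRNA library held 80, 57 and 162 reads there, and the no siRNA library 1, 0 and 0. The largest falls were on chromosome 6 plus strand at 88499357 (160 and 1 reads, 178-fold lower, interval 31.5 to 7086), chromosome 7 minus strand from 13932897 to 13933802 (from 43.7 to 0.930 CPM) and chromosome 16 plus strand at 15682116 (from 63.8 to 1.76). Without siRNA the chromosome 7 and 16 units stood at 10.3 and 12.2 CPM, so the scrambled siRNA library lay well above the other control there. The site at 88499357 stood at 15.6 CPM without siRNA and 18.4 with scrambled siRNA. After CF Im59 siRNA the chromosome 6 site at 88499357 had 0 reads, at least 57.0-fold lower, and the chromosome 16 site was at 1.65 CPM. The third fall after CF Im59 siRNA was on chromosome 8 plus strand at 69156852, from 144 to 3.12 CPM, with 51.9 without siRNA. The rises after CF Im59 siRNA were at the same chromosome 6 site at 12212985 (162 reads against 0, at least 32.7-fold), chromosome 4 plus strand from 134111921 to 134114176 (2 and 174 reads, 65.5-fold, interval 17.9 to 545, and 218 reads with CF Im25 siRNA) and chromosome 7 plus strand at 55330138 (2 and 105 reads, 39.5-fold, interval 10.7 to 331, and 175 reads with CF Im25 siRNA).

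CF Im25 and CF Im68 siRNA changed total reads of the same units more often than independent calls would. Over 11043 units tested in both, 329 were higher in both, where independent calls would share 96.4, and 179 lower in both, where they would share 62.0, with r = 0.298. Pairs of comparisons without a correlation also exceeded independent calls, by less. CF Im59 and CF Im68 siRNA shared 84 higher units against 47.4 and 95 lower units against 59.9. CF Im68 siRNA and no siRNA shared 32 against 20.3 and 42 against 20.0. An excess over independent calls is therefore not by itself a sign of a shared change. CF Im25 and CF Im59 siRNA, with a shared control, had 822 units higher in both, against 112 from independent calls and 66.4 in simulation, and 1087 lower in both, against 214 and 31.8. The covariance was 0.725 against a simulated 0.119, and part of the excess may come from the shared control. With the controls split between the comparisons, r was 0.548 or 0.621. Then 408 or 380 units were higher in both, against 102 or 73.7 from independent calls, and 504 or 485 lower in both, against 125.1 or 98.7.

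The scrambled siRNA libraries of the fragmentation methods differed at more loci than any siRNA changed against its own control. Between the scrambled siRNA libraries of both methods, 1237 of 5014 loci had a higher proximal share with RNase I and 1056 a lower one. The numbering of the deposited files also differs between the methods, so a difference in run or batch cannot be told apart from fragmentation.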

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

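The tests on pairs of nearby sites, on the CF Im59 siRNA library as a control for siRNA in general, and on plus-strand mitochondrial ends were chosen only after the result was seen.

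Against the same control, the median change was 4.19 points after CF Im25 siRNA and of opposite sign, -1.19 points, after CF Im59 siRNA, with -1.15 points for no siRNA; the difference between the siRNAs was not tested. The proximal shift after CF Im25 and CF Im68 siRNA could come from unequal depth, but with all libraries thinned to the smallest total there were 7.70 and 14.6 proximal calls per distal call. Joined neighbouring transcripts do not account for it alone, since pairs of sites under 500 nt apart gave 6.13 and 10.1 proximal calls per distal call. For CF Im25, an effect of any targeting siRNA is argued against by the single CF Im59 siRNA library, with 0.5305 proximal calls per distal call against the same control. No other targeting siRNA was sequenced with RNase I, so this was not tested for CF Im68 and stays open there. An effect of losing CF Im25 or CF Im68 stays open as a hypothesis consistent with these tests, as do off-target effects of each siRNA and differences between single libraries.

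The distal shift after CF Im59 siRNA, at 328 loci, may instead belong to the scrambled siRNA library, since 17.4% of the distal calls passed the same rule against the no siRNA library. Lost calls can also follow from changes close to 20 points, so a small effect of CF Im59 siRNA stays open, and a biological explanation was not tested apart from this.

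Reads on the minus strand of the mitochondrial genome, which the comparisons leave out, made up 8.12% of the CF Im68 siRNA library and 3.93% of its RNase I control, a signal above the control level. In the alkaline libraries they made up 0.930% (no siRNA), 1.33% (scrambled siRNA), 0.542% (CF Im25 siRNA) and 0.810% (CF Im59 siRNA). Most of the excess lay at few positions, with 5.23% against 2.76% at the 10 most read and 6.36% against 3.36% within 1 short window, but few positions do not explain all of it, since outside those 10 the share was 2.48 times that of the control. A loss of nuclear reads would raise both strands, and plus-strand ends were at 1.10 times the control. Fragmentation that ran further in this library could also act on short RNA and was not tested, and an effect of CF Im68 siRNA stays open.

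The following 3 loci were called in opposite directions after CF Im25 and CF Im68 siRNA, were chosen after their values were seen, and the differences were not tested. On chromosome 10 minus strand, 129896873 against 129896161 changed by 22.7 points after CF Im25 siRNA and by -23.4 after CF Im68 siRNA. On chromosome 17 plus strand, 56166812 against 56168584 changed by -20.3 and 28.8 points. On chromosome 7 minus strand, 99016757 against 99014362 changed by 25.4 and -27.1 points.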

How the results depend on the processing

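Other gaps between units, sites from libraries of the same fragmentation method, the rule passed against both controls, removal of sites with at least 95% of reads at 1 nucleotide (6608 of 49965 sites) and thinning for total reads were chosen only after the results were seen, and all alternatives for total reads were applied to units in place of annotated genes. The direction of each comparison's shifts was the same under every alternative run. Proximal calls per distal call ranged from 4.34 to 12.9 for CF Im25, from 8.42 to 20.8 for CF Im68, from 0.470 to 0.807 for CF Im59 and from 0.395 to 0.829 for no siRNA against scrambled siRNA. Of 96 counts of shifts under alternatives, 75 stayed within 1.5 times the main count, as did 30 of 44 counts of totals, and 57 of 66 changes at named loci stayed within their interval. No change at a named locus turned its sign with narrower or wider sites or with thinning. With no siRNA as control none could, since the rule for naming CF Im25 and CF Im59 loci required the same direction.

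With 20 reads as the minimum, more loci were tested, and distal calls rose to 355 (CF Im25), 558 (CF Im59), 202 (CF Im68) and 338 (no siRNA), and proximal calls to 291 (CF Im59) and 171 (no siRNA). Thinning left fewer loci, with means over 10 draws of 115.3 (CF Im25), 208 (CF Im59) and 111.9 (no siRNA) distal calls and 99.7 (CF Im59) and 44.2 (no siRNA) proximal calls. Units ended by gaps over 1 kb hold fewer distant pairs and gave 685 proximal and 108 distal calls (CF Im25), 152 distal (CF Im59), 707 proximal (CF Im68) and 82 distal (no siRNA). With no siRNA as control CF Im59 had 156 distal calls. Passing against both controls left 79 distal calls for CF Im25, and 46 proximal and 57 distal for CF Im59. Sites from the RNase I libraries alone gave 146 distal calls for CF Im68, and the cause was not tested.

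For total reads, no minimum gave 3636 higher and 3660 lower units (CF Im25), 2444 and 3613 (CF Im59), 2037 and 3285 (CF Im68), and 1208 and 2278 (no siRNA). For CF Im68 this reversed the balance of the main counts, 1511 higher and 942 lower. With no siRNA as control CF Im59 had 847 higher units, and the cause was not tested. Thinning gave 1248 higher (CF Im25), 728.2 higher and 1100 lower (CF Im59), 875.7 higher (CF Im68), and 297 and 439.3 (no siRNA), with fewer units tested. Depth limits the CF Im68 comparison, since its control had 5351980 reads. Removal of A-rich sites, the UGUA counts, distinct alignments and a longer downstream reach were not run.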

Other observations

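The tests by chromosome were chosen only after the counts by chromosome were seen, and the comparison of 5 to 10 kb gaps alone was added after the wider test.

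Total reads were also counted apart for units with a single site and with 2 or more sites, without a match on read level and without a test. After CF Im68 siRNA, 15.9% of single-site units were higher and 5.94% lower, against 8.13% and 7.63% of the others. After CF Im25 siRNA the values were 18.1% and 15.3%, against 9.68% and 9.83%, and after CF Im59 siRNA 13.3% and 14.9%, against 5.24% and 8.40%. For no siRNA against scrambled siRNA they were 6.65% and 6.05%, against 2.33% and 2.85%. A unit needed the minimum of reads in either library, and the CF Im68 siRNA library held 10957668 reads in units against 4687930 in its control. With thinning, 48.3% of all changed units were higher after CF Im68 siRNA. Single-site units were not counted apart with thinning, so their excess of higher units cannot be told apart from this difference in depth. On the minus strand of chromosome 8, the sites at 24809889 and 24808480 together held 555 reads with scrambled siRNA, 1426 without siRNA, 6969 with CF Im25 siRNA and 6835 with CF Im59 siRNA, and 6156 and 7649 in the RNase I libraries.

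The ends of reads were spread over more nucleotides in the RNase I libraries, where a difference in library preparation or run is not excluded. At 2343 sites with at least 200 reads in every library, a median of 62.6% to 64.4% of the reads lay at the peak nucleotide in the alkaline libraries, and 53.7% and 52.1% in the RNase I libraries with scrambled and CF Im68 siRNA.

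A hypothesis was that the proximal shift also reaches sites more than 5 kb upstream, in which case neighbouring units 5 to 20 kb apart would show at least 2 upstream calls per downstream call. They showed 1.23 after CF Im25 siRNA (interval 1.04 to 1.44) and 1.11 after CF Im68 siRNA (interval 0.893 to 1.39), which argues against a ratio of 2 over that whole range. No siRNA against scrambled siRNA gave 0.705, and CF Im25 siRNA against no siRNA 1.42. Gaps of 5 to 10 kb alone gave 1.56 after CF Im25 siRNA, 2.16 with no siRNA as its control, and 1.71 after CF Im68 siRNA, against 0.588 for no siRNA against scrambled siRNA. Gaps of 10 to 20 kb gave 0.994 after CF Im25 siRNA, 1.02 with no siRNA as its control, and 0.685 after CF Im68 siRNA, against 0.817 for no siRNA against scrambled siRNA. The prediction was written for the whole range, and an effect over gaps of 5 to 10 kb stays open.

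Another hypothesis was that chromosomes 16 and 19 had few proximal shifts because of the distance between their sites. Given the distances, observed over expected shifts were 0.5125 after CF Im25 siRNA (interval 0.3995 to 0.648) and 0.4053 after CF Im68 siRNA (interval 0.302 to 0.533), so distance does not explain the low counts. Joined neighbouring transcripts are a candidate explanation that stays open. Among pairs under 500 nt apart the ratios were 0.5568 (interval 0.288 to 0.973) and 0.4537 (interval 0.196 to 0.894), from 12 and 8 shifts. Even at the upper bounds these close pairs had fewer shifts than expected. The upper bounds did not fall below the stricter limit written beforehand for this explanation, so the planned rule could not decide. Sequence composition was not tested.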
